A study of Homo sapiens with 18 samples.

How the data were processed

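RNA was measured in 18 libraries from 2 human melanoma cell lines, A375 and M14. Each line had been treated for 48 h with DMSO, the solvent control, or with 1 of 2 compounds named QNC and MBZ in the labels, each at 2 µM. Each of the 6 groups holds 3 libraries, and the labels call these biological replicates. Nothing further is stated about separate cultures, so p-values measure the spread between these samples. The sample labels give 0.1% DMSO and the series text gives 0.01%, and this difference could not be settled here. Samples that received both compounds together were not analysed here.

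Per the labels' protocols, libraries were prepared from 250 ng of total RNA with a QuantSeq FWD kit, which primes on poly(A) tails and reads from the 3′ part of a transcript. They were sequenced from 1 end with 100 nt reads on an Illumina NovaSeq instrument. Per the submitters' processing notes the genome build was hg38, and the aligner and the counting tool are not given in the sources used here. The deposited values are estimated counts per gene, with decimals, in 1 table of the whole series, not normalized. The protocol fixed before the data were examined assumed whole counts, so the estimated counts were rounded to whole numbers before the count tests. Because reads come from the 3′ part, counts were not divided by gene length.

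The table holds 60617 Ensembl gene identifiers. Of these, 42000 were matched to a symbol by identifier and 58542 were found in GENCODE v29, whose GRCh38 (hg38) positions are given, counted from 1. All 18 columns were used, and 0 lines of the table name no gene. Strand use in the counting is not stated, so overlapping and antisense genes cannot be told apart. Near-identical gene copies, such as the U1 RNA genes, histone genes and the RGPD family, are reported as uncertain, since the counting may divide or repeat their reads. In all 18 libraries, 3 non-coding genes hold an identical value.

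The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors, filterByExpr and robust estimation of the spread. One model of 6 group means was fitted to all 18 libraries, and 9 contrasts were taken: each compound against DMSO in each line, MBZ against QNC in each line, the difference between the lines in the response to each compound, and the DMSO groups against each other. After the filter, 15764 genes were tested, with a common biological coefficient of variation of 0.206. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Levels are CPM, counts per 1e6 of the effective library size, as mean ± SD over 3 libraries. Changes are log2 fold changes ± SE (standard error), with n = 3 libraries per group unless stated. The SE is the absolute log2 fold change divided by the square root of the test's F value. It therefore rests on the spread estimated over all libraries of the fit, not only on those compared.

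Before the data were examined, 31 gene lists were fixed, drawn from textbook knowledge of the lines and of drug responses, with markers of other cell types among them. Each list was tested with camera at a preset correlation between genes of 0.01, which compares the list with the other genes tested, and its p was adjusted over 31 lists and 9 contrasts, 279 tests. Camera with an estimated correlation is given beside it, and of the 95 tests that passed with the preset value, 1 passed with the estimated one. Counts of members are given over all genes tested and again adjusted over the list alone, written "alone" after the first use. In each compound against DMSO contrast, the genes named are the 6 higher and 6 lower with the largest change among called genes with a symbol, at least 20 CPM in the higher group and all 3 treated libraries beyond all 3 DMSO libraries. Up to 4 members per described list, those with the smallest p, and 14 genes fixed in advance are also named. In the other contrasts 5 genes per direction are named, without the condition on single libraries where the responses of the lines are compared.

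Other settings fixed in advance were DESeq2 1.42.0 with its own size factors, RLE factors, no filter on low counts, limma voom, only the libraries of the line or groups compared, the replicate number as a term, and leaving out each library in turn. Chosen after seeing the data were a fit on 17 libraries without the library labelled M14 QNC replicate 1, the same with thinned counts, all 18 libraries thinned to the total of the shallowest, protein-coding genes only, and counts from which each library's estimated share of the other line's DMSO profile was subtracted. That share is the median, over genes at least 100 times higher in the other line's DMSO group and at least 20 CPM there, of the level relative to the other line's DMSO mean. Only its excess over the mean share of the line's own DMSO libraries was subtracted. The share was estimated on TMM-scaled levels but removed by raw library totals. MBZ libraries had lower TMM factors than the other line's DMSO libraries (0.543 to 0.887 against 1.20 to 1.28 for A375 MBZ, 0.735 to 1.03 against 1.16 to 1.22 for M14 MBZ). More than the estimated share was therefore removed from them. Comparisons against the same DMSO libraries share chance values. Unchanged groups were therefore simulated 20 times, with all libraries of a line, DMSO included, drawn from its DMSO means.

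The procedure was tested on simulated counts drawn from the real means and library totals with 200 changed genes. With edgeR in A375 QNC against DMSO, 52 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were recovered, and 9 of the unchanged genes were called among 15365 tested. In M14 MBZ against DMSO, the numbers were 55 and 93 of 100, with 6 unchanged genes called among 15345, against 129 with limma voom. No pair of libraries agreed within sampling noise (chi-square per degree of freedom at least 4.12 within groups and 27.3 across groups), so all 18 were counted as separate samples. Intervals of ratios at low counts are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only. These ratios use raw library totals, without TMM factors, so they differ from the fold changes of the fit.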

Results

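The libraries differed in depth and in the kinds of RNA they held. Library totals were 14.4 ± 3.47 (in units of 1e6 counts) in A375 DMSO, 13.1 ± 3.53 after QNC and 6.81 ± 1.78 after MBZ. In M14 they were 24.8 ± 1.98, 14.6 ± 6.03 and 3.12 ± 2.53 (mean ± SD, n = 3 each). The 2 mitochondrial ribosomal RNAs took 13.8 ± 3.21% of counts in A375 DMSO and 38.0 ± 8.46% after MBZ, and 11.2 ± 0.527% and 21.4 ± 2.08% in M14 (exact permutation p = 0.1 in each line, the smallest possible with 3 against 3). After QNC their share was 19.5 ± 3.57% in A375 and 14.1 ± 4.39% in M14 (exact permutation p = 0.2 and 0.4). Protein-coding genes held 69.9 ± 2.57% of counts in A375 DMSO and 39.6 ± 11.7% after MBZ, and 75.8 ± 1.63% and 50.4 ± 7.74% in M14 (exact permutation p = 0.1 in each line). After QNC they held 61.8 ± 4.32% in A375 and 61.1 ± 13.8% in M14 (exact permutation p = 0.1 and 0.3). The library labelled M14 QNC replicate 1 lies near the M14 DMSO libraries: its Spearman correlation across genes was 0.991 to 0.993 with them and 0.967 to 0.969 with the other 2 M14 QNC libraries.

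**Figure D1:**
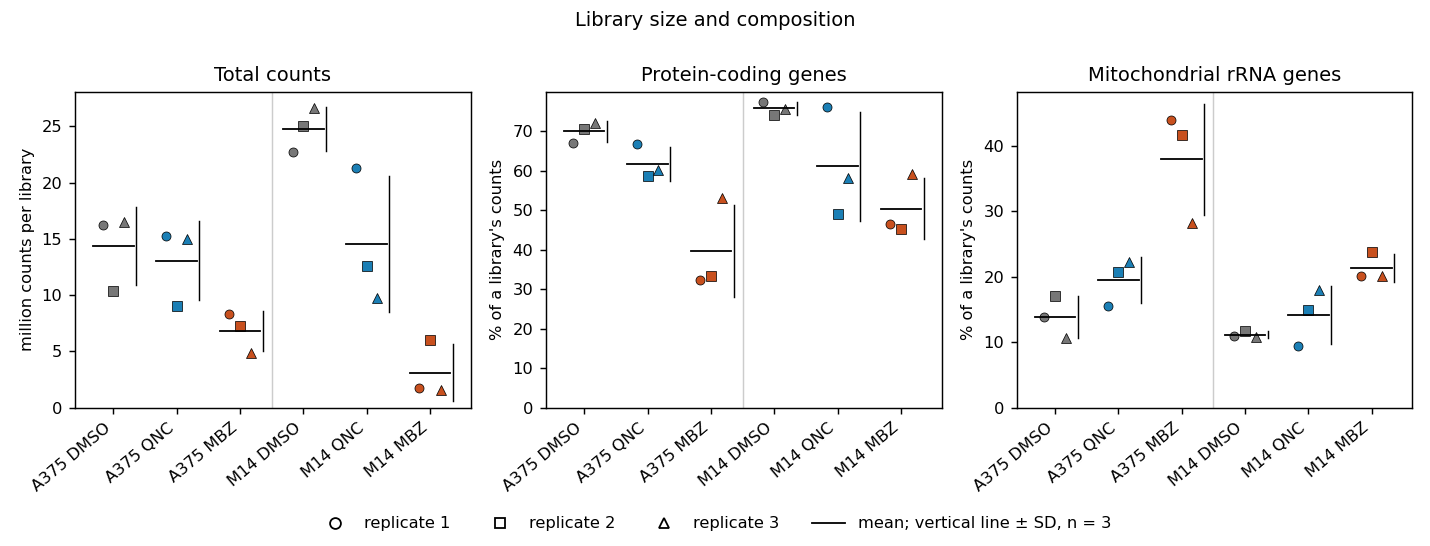
Library totals, percent of counts on protein-coding genes and percent on the 2 mitochondrial ribosomal RNAs. Each point is a library and bars show mean ± SD of 3 libraries per group.

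How do the 2 lines differ before treatment? M14 held pigment-cell transcripts at far higher levels than A375: MLANA, a melanosome antigen (chromosome 9, 5890802 to 5910606), lay at 316 ± 38.4 CPM in M14 and 0.763 ± 0.175 CPM in A375 (log2 fold change 8.71 ± 0.88, SE). OCA2, a melanosome ion transport protein, differed by 8.63 ± 0.33 (5261 against 7 counts, ratio 436, 95% interval 211 to 1085). GPR143, a melanosome receptor, differed by 8.84 ± 0.63 (10229 against 12, 495, 283 to 957), and PMEL, which forms melanosome fibrils, by 6.22 ± 0.43. LY75, an endocytic receptor, was higher by 9.80 ± 0.85 (13604 against 8 counts, 987, 501 to 2286), and the non-coding LINC01443 by 8.91 ± 0.43 (4670 against 5, 542, 232 to 1670). A375 held SOX9, a neural crest transcription factor (chromosome 17, 72121020 to 72126420), at 163 ± 37.8 CPM against 0.256 ± 0.168 in M14 (−9.29 ± 0.44). Also lower in M14 were SNPH, a protein that anchors axonal mitochondria (−10.14 ± 0.46, 2 against 1745 counts, ratio of A375 to M14 1504, 416 to 12429), SHISAL1 (−9.84 ± 0.36, 6 against 3454, 992, 455 to 2706), the lipase LPL (−9.60 ± 0.58, 9 against 4425, 848, 446 to 1855) and GDNF, a neurotrophic factor (−9.33 ± 0.45, 4 against 1714, 739, 288 to 2714).

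Of 33 melanocyte lineage genes tested, 21 were higher and 3 lower in M14 (adjusted over the list alone 23 and 3, median log2 fold change 1.57, camera adjusted p = 1.72e-07, adjusted p = 0.601 with an estimated correlation). Of 32 glycolysis and hypoxia genes, 27 were higher and 1 lower (alone 28 and 1, median 1.17, p = 2.81e-07, adjusted p = 0.12 with an estimated correlation), among them BNIP3 (2.69), PDK1 (2.31) and P4HA1 (1.98). Matrix genes were mostly lower in M14, 19 of 30 with 3 higher (alone 21 and 3, median −1.40, p = 1.44e-05, adjusted p = 0.184 with an estimated correlation), such as the collagens COL5A2 (−8.35), COL6A2 (−6.95) and COL6A1 (−4.82). Lower too were 24 of 38 interferon response genes, with 3 higher (alone 26 and 3, median −1.75, p = 0.000665, adjusted p = 0.684 with an estimated correlation), among them MX2 (−7.12), IRF7 (−5.06) and MX1 (−4.25). Of 31 p53 targets, 23 were lower and 2 higher (alone 24 and 2, median −1.26, p = 6.11e-07, adjusted p = 0.127 with an estimated correlation), including MDM2, which marks p53 for degradation (−2.73), BTG2 (−3.47) and RRM2B (−2.35). Across all genes 3698 were higher and 3964 lower in M14.

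QNC in A375: which genes moved after 48 h? Transcripts of cell division fell. KIF20A, a kinesin of the spindle midzone (chromosome 5, 138178719 to 138187715), went from 73.2 ± 17.2 to 12.3 ± 0.641 CPM (log2 fold change −2.57 ± 0.20, SE, n = 3 against 3). PLK1, a mitotic kinase (chromosome 16, 23677656 to 23690367), fell from 26.3 ± 3.57 to 4.32 ± 0.621 CPM (−2.62 ± 0.22), and UBE2C, an enzyme that marks cyclins for degradation (chromosome 20, 45812576 to 45816957), from 52.0 ± 16.1 to 8.07 ± 1.3 CPM (−2.69 ± 0.24). CCNB1, the cyclin of entry into mitosis, fell by 2.06 ± 0.19 on the log2 scale, MKI67, a proliferation marker, by 2.26 ± 0.21 and NEK2, a centrosome kinase, by 2.57 ± 0.22. MDM2 (chromosome 12, 68808176 to 68850686) rose from 358 ± 23.4 to 774 ± 227 CPM (1.11 ± 0.23).

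In A375 after QNC, all 40 mitosis genes tested fell, and 40 when adjusted over the list alone (median −1.92, camera adjusted p = 3.02e-156, adjusted p = 0.01 with an estimated correlation). Of 42 DNA replication genes 10 fell and 32 did not pass (alone 24 fell, median −0.70, p = 2.72e-16, adjusted p = 0.5 with an estimated correlation), with CDT1, which licenses origins (−2.15 ± 0.19), TK1 (−1.69 ± 0.25) and ORC1 (−1.52 ± 0.26). Of 23 histone genes 8 fell (alone 18, median −1.14, p = 4.52e-13, adjusted p = 0.473 with an estimated correlation), such as H1-5 (−1.82 ± 0.28) and H2AX (−1.66 ± 0.33), with reads of near-identical copies uncertain. Of 31 p53 targets 4 rose (alone 13, median 0.42, p = 2.44e-07, adjusted p = 0.127 with an estimated correlation): MDM2, the repair factor DDB2 (0.91 ± 0.16), the nucleotide reductase subunit RRM2B (0.89 ± 0.18) and the apoptosis effector BAX (0.84 ± 0.21). CDKN1A, which halts the cell cycle, lay higher in 3 of 3 libraries (520 ± 58.5 against 286 ± 20.5 CPM) without passing (0.86 ± 0.34, adjusted p = 0.205), and passed at the same fold without the library labelled M14 QNC replicate 1 (SE 0.16, adjusted p = 0.00169). Tubulins fell in 2 of 15 (alone 3, median −0.32, p = 0.00554, adjusted p = 0.645 with an estimated correlation), TUBB (−1.03 ± 0.22) and TUBA1B (−1.19 ± 0.31). ER chaperones fell in 3 of 24 (alone 5, median −0.32, p = 0.000296, adjusted p = 0.5 with an estimated correlation), among them HSP90B1 (−0.79 ± 0.19). Of 31 dedifferentiation genes 3 fell (alone 4, median −0.22, p = 0.00766, adjusted p = 0.473 with an estimated correlation): VIM (−0.98 ± 0.18), POU3F2 (−0.94 ± 0.19) and ZEB2 (−0.69 ± 0.19). Of 27 YAP and SRF targets 1 fell, CCN2 (−1.81 ± 0.42; alone 1 rose and 3 fell, median −0.23, p = 0.0223, adjusted p = 0.5 with an estimated correlation).

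The largest rise among named genes was that of CYP1A1, a target of the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), from 11.8 ± 0.498 to 54.1 ± 35.0 CPM (2.19 ± 0.41). After it came PTCHD4 (1.43 ± 0.31), the neuropeptide precursor TAC1 (1.34 ± 0.25), the non-coding GCAWKR (1.29 ± 0.23) and DNHD1 (1.26 ± 0.32). Also among the largest falls were RGPD5 (−2.82 ± 0.56) and the histone gene H3C14 (−2.56 ± 0.55), both with near-identical copies. MITF, the main melanocyte transcription factor (0.12), PMEL (0.50), DUSP6 (0.23), FOSL1 (−0.65), DDIT3 (0.15), HMGCS1 (−0.13), CXCL8 (−0.28) and HMOX1 (0.27) did not pass (adjusted p 0.312 to 0.93). In total 131 genes rose and 323 fell (64 and 218 of them at least 2-fold). With DESeq2 these were 359 and 487, and with thinned counts 37 and 171. Leaving out 1 of the 6 libraries compared ended the call of TUBA1B in all 6 cases, those of DNHD1, H3C14, BAX, ZEB2 and CCN2 in 5, HSP90B1 in 4, RGPD5 in 3, TUBB in 2, and PTCHD4 and H2AX in 1. TUBA1B also missed the threshold without the library labelled M14 QNC replicate 1 (adjusted p = 0.0674).

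**Figure D2:**
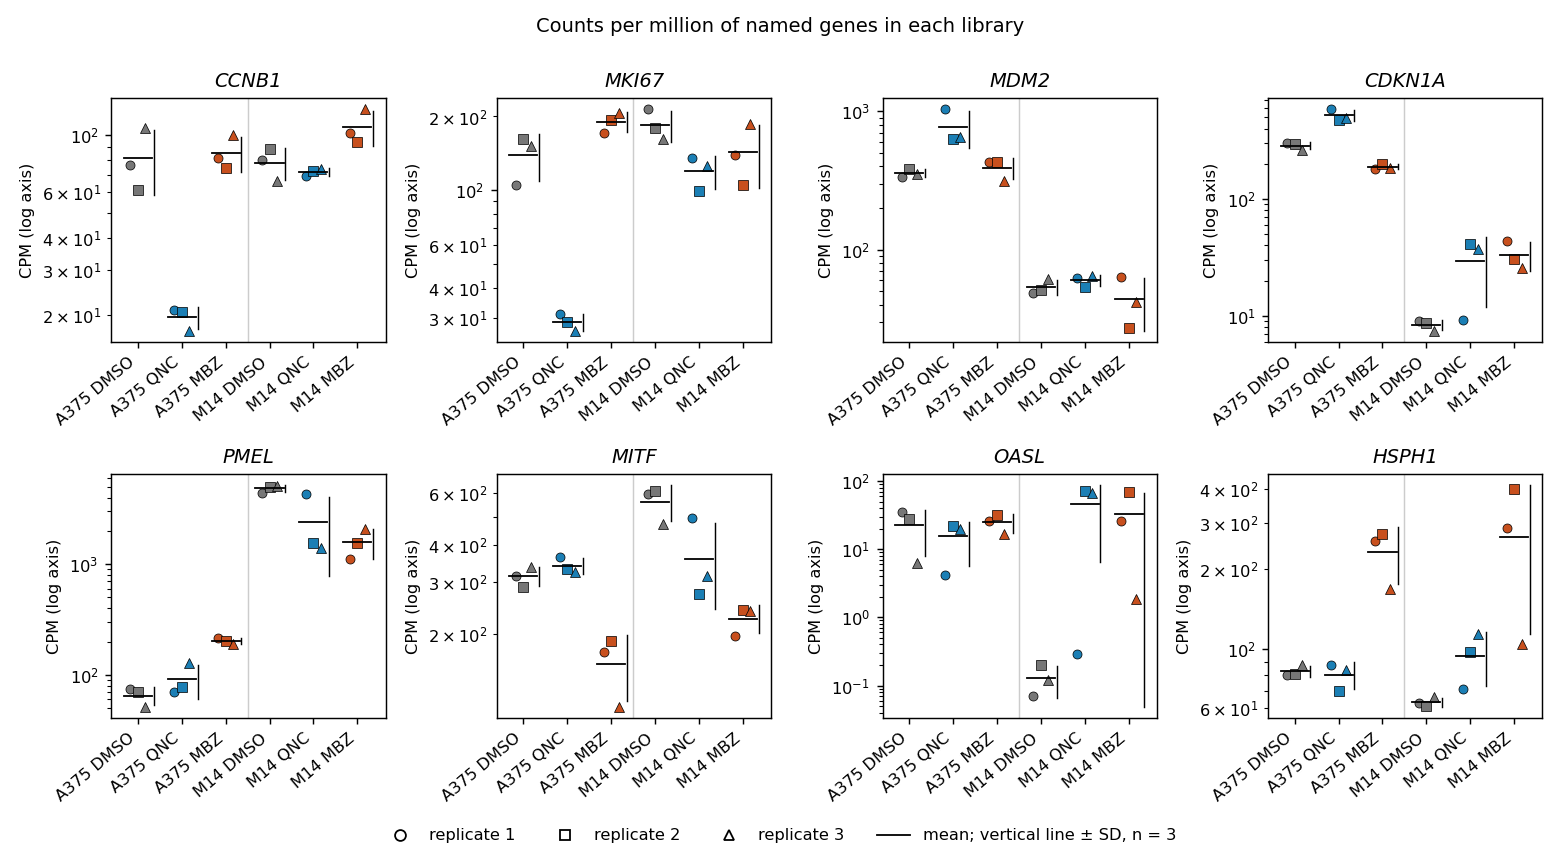
CPM on a log axis of 8 named genes of cell division, p53, pigment, interferon and heat shock in each of the 18 libraries. Bars show mean ± SD of 3 libraries, and SD bars that would reach below the axis stop at it.

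QNC in M14, the same question: over all 18 libraries 7 genes rose and 0 fell (edgeR). Among them were SLC7A11, the cystine importer (chromosome 4, 138164097 to 138242349), from 37.8 ± 6.18 to 98.9 ± 36.3 CPM (log2 fold change 1.38 ± 0.25), and 3 small non-coding RNAs, SCARNA10 (2.99 ± 0.37), SNORD3A (2.25 ± 0.30) and RPPH1 (2.08 ± 0.35). Leaving out 1 of the 6 libraries ended the call of SLC7A11 in 5 cases and that of RPPH1 in 4. Lower in the QNC group, short of the threshold, were PMEL (−0.998, adjusted p = 0.199), MITF (−0.64, 0.156) and MKI67 (−0.62, 0.15). CDKN1A (1.79 ± 0.36, 0.0706), FOSL1 (1.21, 0.0973), HMOX1 (1.79, 0.274), DDIT3 (1.39, 0.269), CXCL8 (1.10, 0.23) and MDM2 (0.16, 0.792) lay higher without passing, and CCNB1 lay at −0.12 (0.806). TUBB (−0.44), TUBA1B (−0.50), DUSP6 (0.29) and HMGCS1 (0.01) did not pass either. CDKN1A stood at 9.25 CPM in the library labelled replicate 1 and at 41.2 and 37.6 in the other 2, against 8.36 ± 0.865 in DMSO. OASL, an interferon-induced gene, stood at 0.291, 72.0 and 67.3 CPM (8.36 ± 1.88, adjusted p = 0.09). Unadjusted p was under 0.05 for 1225 higher and 1157 lower genes, and DESeq2 called 267 and 95, limma voom 5 and 0.

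Over 18 libraries in M14 QNC, 0 of 33 melanocyte lineage genes passed, and the list lay lower than other genes (alone 7 fell, median −0.71, camera adjusted p = 1.89e-11, adjusted p = 0.473 with an estimated correlation). So did the 39 lysosome genes (0 passed, alone 20 fell, median −0.58, camera adjusted p = 4.3e-16, adjusted p = 0.347 with an estimated correlation). The 47 oxidative phosphorylation genes lay lower too (0 passed, alone 23 fell, median −0.45, camera adjusted p = 2.47e-17, adjusted p = 0.554 with an estimated correlation). Of 35 integrated stress response genes 1 rose (alone 14, median 0.65, camera adjusted p = 1.49e-08, adjusted p = 0.5 with an estimated correlation). Of 40 mitosis genes 0 passed (alone 0, median −0.22, camera adjusted p = 0.00112, adjusted p = 0.841 with an estimated correlation), and of 31 p53 targets 0 (alone 6 rose, median 0.26, camera adjusted p = 0.0224, adjusted p = 0.565 with an estimated correlation). No member passed of the other lists that lay higher. These were ER chaperones (24 tested, alone 5 rose, median 0.33, camera adjusted p = 0.000462, adjusted p = 0.5 with an estimated correlation) and interferon response (38, alone 12 rose and 1 fell, 0.55, 0.000413, adjusted p = 0.662 with an estimated correlation). They also included MAPK output (29, alone 9 rose and 1 fell, 0.40, 0.000139, adjusted p = 0.576 with an estimated correlation) and NF-kB with cytokines (21, alone 0, 0.72, 6.6e-05, adjusted p = 0.601 with an estimated correlation). Epithelial markers, fixed as markers of another cell type, were the last of them (9, alone 6 rose, 1.96, 0.000241, adjusted p = 0.516 with an estimated correlation).

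Without the library labelled M14 QNC replicate 1, a setting chosen after seeing the data, 954 genes rose and 1191 fell in M14 QNC (2 against 3 libraries). It was left out because it lies near DMSO, which by itself makes the groups more different, so these values describe the other 2 libraries only. In those 2, protein-coding genes held 49.1 and 58.0% of counts. Signal recognition particle, 7SK, RNase P (RPPH1) and RNase MRP RNA together held 21.8 and 18.1% (6.19 to 8.06% in M14 DMSO). Pigment genes fell: DCT, a melanin synthesis enzyme (chromosome 13, 94436808 to 94479682), from 1844 ± 89.6 to 295 ± 22.7 CPM (−2.64 ± 0.24), PMEL from 4795 ± 332 to 1453 ± 118 CPM (−1.72 ± 0.26), TRPM1 (−2.57 ± 0.29), MLANA (−2.42 ± 0.38) and MITF (−0.94 ± 0.20). In this fit 26 of 33 melanocyte lineage genes fell (alone 26, 1 rose, median −1.33, p = 2.22e-31, adjusted p = 0.00667 with an estimated correlation). Of 39 lysosome genes 27 fell (alone 30, median −1.02, p = 1.46e-21, adjusted p = 0.0603 with an estimated correlation), such as ASAH1, the acid ceramidase (−2.01 ± 0.23), and the cathepsin CTSA (−1.63 ± 0.20). Of 47 oxidative phosphorylation genes 29 fell (alone 43, median −0.69, p = 1.63e-18, adjusted p = 0.408 with an estimated correlation), including ATP5F1C (−1.15 ± 0.19). OASL (chromosome 12, 121019111 to 121039242) rose from 0.129 ± 0.0653 to 68.7 ± 3.26 CPM (8.95 ± 1.29, with 12 counts in the 3 DMSO libraries together), with the chemokine CCL5 (7.29 ± 1.09), IFIT2 (6.57 ± 1.01) and IFIT3 (4.98 ± 0.74). In all 15 of 38 interferon response genes rose and 1 fell (alone 17 and 1, median 0.82, p = 1.2e-05, adjusted p = 0.523 with an estimated correlation).

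Further in this fit, 15 of 35 stress response genes rose (alone 18, 1 fell, median 0.81, p = 4.18e-09, adjusted p = 0.397 with an estimated correlation): SESN2 (3.08 ± 0.29), CHAC1, which degrades glutathione (3.13 ± 0.43), and DDIT4 (1.56 ± 0.25). ER chaperones rose in 8 of 24 (alone 10, median 0.40, p = 0.000294, adjusted p = 0.397 with an estimated correlation), with HSPA5 at 2.48 ± 0.41 and XBP1, a transcription factor of ER stress, at 1.18 ± 0.23. CDKN1A rose by 2.23 ± 0.18 and the p53 target PMAIP1 by 3.12 ± 0.27. Of 31 p53 targets 9 rose and 2 fell (alone 10 and 4, median 0.13, p = 0.00384, adjusted p = 0.419 with an estimated correlation). Of 29 MAPK output genes 11 rose and 1 fell (alone 11 and 1, median 0.57, p = 1.48e-05, adjusted p = 0.397 with an estimated correlation), such as EREG (4.05 ± 0.60) and FOSL1 (1.57 ± 0.21). MKI67 fell by 0.73 ± 0.22 on the log2 scale and CCNB1 stood at −0.10 (adjusted p = 0.789). Of 11 epithelial markers 5 rose (alone 7, median 2.30, p = 2.62e-06, adjusted p = 0.148 with an estimated correlation), among them the keratins KRT19 (4.41 ± 0.63) and KRT17 (4.30 ± 0.65).

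**Figure D3:**
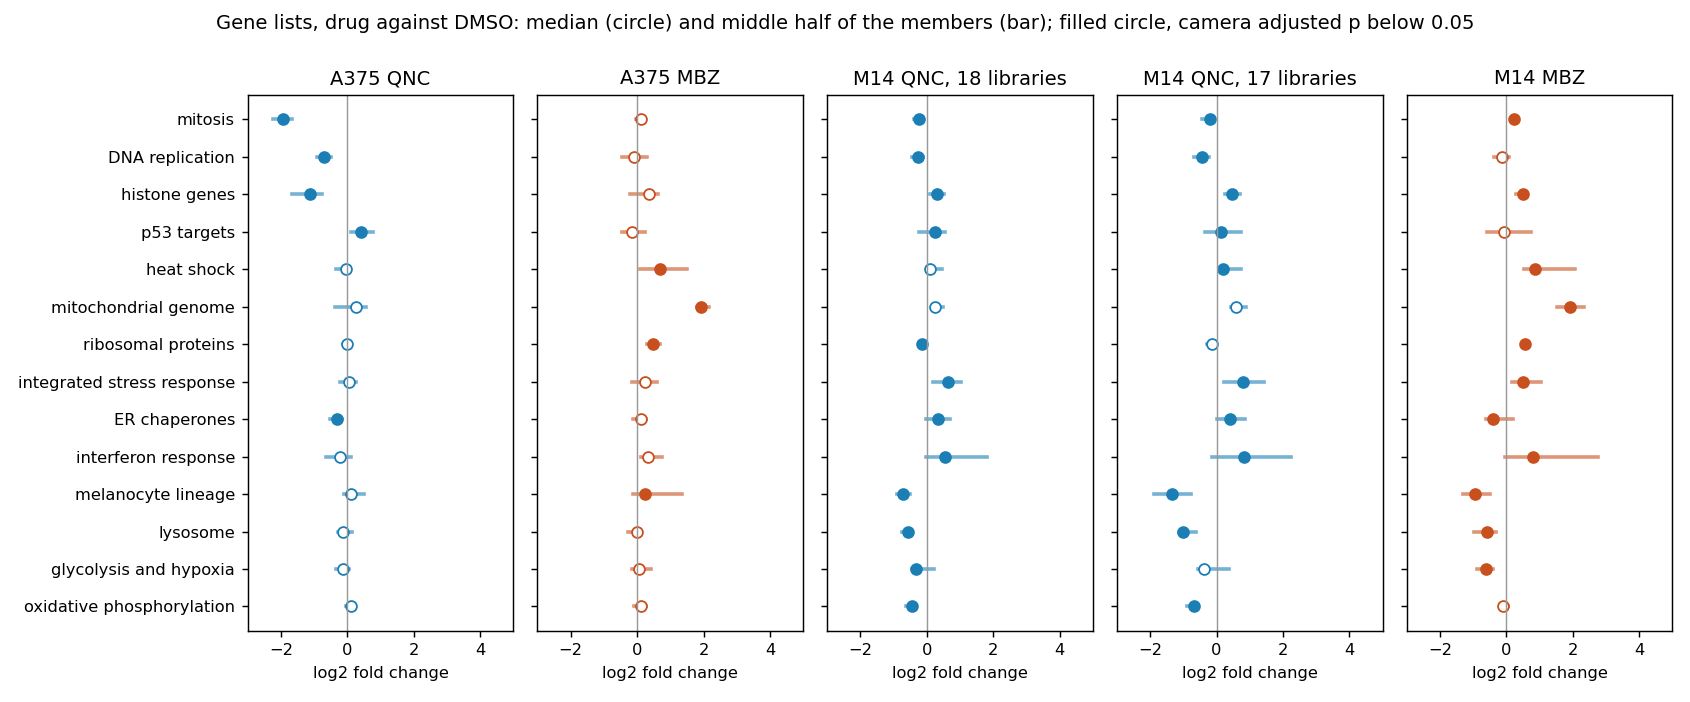
Median and middle 50% of log2 fold changes of 14 gene lists in the 4 compound against DMSO comparisons, M14 QNC with 18 and with 17 libraries. Filled points mark camera adjusted p under 0.05 with the preset correlation.

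MBZ in A375, the same question: among the genes that rose were some encoded in mitochondria and some of protein folding. MT-CO1, a subunit of cytochrome oxidase encoded in mitochondria, rose by 2.93 ± 0.38 on the log2 scale and MT-CO3 by 2.37 ± 0.29. The heat shock proteins HSP90AA1 (1.34 ± 0.20) and HSPH1 (1.49 ± 0.32) rose, with the mitochondrial chaperonin partner HSPE1 (1.30 ± 0.24) and the HSP90 partner CHORDC1 (1.502 ± 0.32). MIR222HG, host transcript of 2 microRNAs (chromosome X, 45745211 to 45770274), went from 2.09 ± 0.383 to 30.8 ± 14.4 CPM (3.89 ± 0.42). SCARF2, a scavenger receptor (chromosome 22, 20424815 to 20437826), fell from 36.1 ± 3.42 to 7.51 ± 0.597 CPM (−2.26 ± 0.22).

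In A375 after MBZ, 10 of 13 genes of the mitochondrial genome rose (alone 11, median 1.91, camera adjusted p = 2.44e-07, adjusted p = 0.5 with an estimated correlation), in libraries where mitochondrial ribosomal RNA took 38.0% of counts. Of 68 ribosomal protein genes 33 rose (alone 40, median 0.49, p = 4.55e-10, adjusted p = 0.663 with an estimated correlation), for example RPL34 (0.95 ± 0.16) and RPS24 (0.86 ± 0.17). Heat shock genes rose in 11 of 21 (alone 12, 2 fell, median 0.70, p = 0.000768, adjusted p = 0.5 with an estimated correlation). Of 33 melanocyte lineage genes 6 rose and 2 fell (alone 6 and 2, median 0.25, camera adjusted p = 0.0434, adjusted p = 0.843 with an estimated correlation). MITF (chromosome 3, 69739435 to 69968337) fell from 314 ± 24.2 to 159 ± 40.3 CPM (−0.98 ± 0.21). PMEL (chromosome 12, 55954105 to 55973317) rose from 64.9 ± 12 to 203 ± 13.9 CPM (1.64 ± 0.36), OCA2 by 3.36 ± 0.53 (19 against 7 counts, ratio 5.73, 2.30 to 16.1) and GPR143 by 4.23 ± 0.77 (59 against 12, 10.4, 5.52 to 21.2). The ratios use raw library totals and the log2 values TMM factors. These 3 are far higher in M14, and M14 transcripts stood in the A375 MBZ libraries at 3.06 to 4.03% of their M14 level, against 0.320 to 0.602% in the A375 DMSO libraries. With that share subtracted the 3 turned lower and the list no longer passed (adjusted p = 0.72). The subtraction removed more than the estimated share from these libraries, so the turned signs cannot be read as falls.

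Cytokine genes rose in 5 of 21 (alone 6, median 0.82, camera adjusted p = 0.116), with NFKBIZ, an NF-kB cofactor (2.28 ± 0.27), and the chemokines CXCL1 (1.69 ± 0.30) and CXCL3 (1.77 ± 0.55). Of 15 AP-1 subunits 2 rose and 4 fell (alone 2 and 4, median 0.01, mean 0.21, test lower, camera adjusted p = 0.646): FOS rose by 3.52 ± 0.79 while JUND (−1.32 ± 0.31) and MAFK (−1.35 ± 0.30) fell. Stress response genes moved both ways, 4 up and 3 down of 35 (alone 2 and 1, camera adjusted p = 0.508), with PPP1R15A (1.93 ± 0.52), DDIT3 (1.70 ± 0.57) and NUPR1 (1.23 ± 0.29) higher and the amino acid transporter SLC7A5 lower (−0.91 ± 0.19). Of 25 cholesterol synthesis genes 4 rose and 1 fell (alone 4 and 1, camera adjusted p = 0.66), HMGCS1 by 1.73 ± 0.45. Among glycolysis and hypoxia genes 5 of 32 rose (alone 5, camera adjusted p = 0.34), ADM, a vasodilator peptide, by 2.00 ± 0.30. Of 40 mitosis genes 1 rose (alone 0, camera adjusted p = 0.409), and CCNB1 (0.06, adjusted p = 0.848) and MKI67 (0.45, 0.0991) did not pass. DNA replication genes had 1 rise and 4 falls of 42 (alone 0 and 2, camera adjusted p = 0.388), among the falls CDT1 (−1.02 ± 0.20) and FEN1 (−1.06 ± 0.24).

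Among the largest changes, 5 U1 RNA gene copies (RNU1-28P, RNU1-27P, RNU1-1, RNVU1-18 and RNU1-2) share 1 value, a rise from 59.1 ± 23.7 to 822 ± 502 CPM (3.80 ± 0.69). Falls included NAT8L (−2.15 ± 0.31), FAM20C, a secreted-protein kinase (−2.12 ± 0.25), CBX2, a Polycomb protein (−2.03 ± 0.27), the calcium channel CACNA1H (−1.92 ± 0.25) and BAHCC1 (−1.86 ± 0.26). CDKN1A (−0.61), MDM2 (0.13), TUBB (0.30), TUBA1B (0.22), DUSP6 (0.20), FOSL1 (0.75), CXCL8 (0.70) and HMOX1 (−0.30) did not pass (adjusted p 0.0878 to 0.817). Without the library labelled M14 QNC replicate 1, CDKN1A (−0.61, adjusted p = 0.00582) and FOSL1 (0.74, adjusted p = 0.0059) passed. In total 1964 genes rose and 1942 fell. Without the filter on low counts 1849 rose and 3653 fell, with a median shift of −0.26 over all genes, and thinned to the shallowest library 856 and 663. Leaving out 1 of 6 libraries ended the calls of DDIT3 and HMGCS1 in 4 cases each and those of CXCL3 and PPP1R15A in 2.

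MBZ in M14: among the genes that rose were heat shock proteins and CDKN1A, and among those that fell were MITF and PMEL. HSP90AA1 rose by 1.64 ± 0.21, HSPH1 by 2.08 ± 0.32 and the small heat shock protein CRYAB by 3.83 ± 0.64. CDKN1A (chromosome 6, 36676460 to 36687339) went from 8.36 ± 0.865 to 33.4 ± 9.31 CPM (1.98 ± 0.38) and HMOX1, a heme-degrading enzyme, rose by 3.80 ± 0.78. MITF fell by 1.31 ± 0.21 and PMEL by 1.60 ± 0.35 on the log2 scale. SDC3, a cell surface proteoglycan (chromosome 1, 30869467 to 30908761), fell from 581 ± 49.0 to 119 ± 18.9 CPM (−2.29 ± 0.23), and APOLD1 (chromosome 12, 12725917 to 12829975) from 120 ± 19.5 to 21.1 ± 7.84 CPM (−2.60 ± 0.32).

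In M14 after MBZ 13 of 21 heat shock genes rose (alone 16, median 0.86, camera adjusted p = 2.89e-11, adjusted p = 0.127 with an estimated correlation). Mitochondrial genome genes rose in 9 of 13 (alone 12, median 1.91, p = 8.46e-10, adjusted p = 0.473 with an estimated correlation), MT-CO3 by 2.33 ± 0.28, with mitochondrial ribosomal RNA at 21.4% of counts. Of 68 ribosomal protein genes 42 rose (alone 56, median 0.56, p = 3.4e-17, adjusted p = 0.576 with an estimated correlation), for example RPL31 (0.89 ± 0.18). Of 33 melanocyte lineage genes 14 fell (alone 17, median −0.94, p = 2.81e-07, adjusted p = 0.601 with an estimated correlation), with MYO5A, which carries melanosomes (−1.48 ± 0.26), ERBB3 (−1.16 ± 0.22) and SOX10, a melanocyte lineage factor (−0.90 ± 0.19). Glycolysis and hypoxia genes fell in 15 of 32 with 1 rise (alone 17 and 1, median −0.60, p = 1.45e-05, adjusted p = 0.184 with an estimated correlation): P4HA1 (−1.40 ± 0.18), PDK1 (−1.21 ± 0.21) and PGK1 (−1.19 ± 0.20) fell and ALDOC rose (3.75 ± 0.36). Lysosome genes fell in 16 of 39 and rose in 2 (alone 22 and 2, median −0.58, p = 2.59e-05, adjusted p = 0.662 with an estimated correlation), among them PSAP (−1.39 ± 0.23) and the cathepsin CTSB (−1.06 ± 0.21). Of 24 ER chaperones 7 fell and 1 rose (alone 7 and 1, median −0.40, p = 0.037, adjusted p = 0.689 with an estimated correlation), with SEL1L, of ER-associated degradation, at −1.37 ± 0.16. Of 16 fatty acid synthesis genes 6 fell (alone 6, median −0.37, p = 0.00644, adjusted p = 0.576 with an estimated correlation), the desaturase SCD by 1.47 ± 0.26 on the log2 scale.

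Interferon response genes rose in 9 of 38 and fell in 2 (alone 14 and 2, median 0.81, p = 0.00068, adjusted p = 0.663 with an estimated correlation), led by OASL (7.99 ± 1.91, 32.3 ± 34.3 against 0.130 ± 0.0658 CPM, 349 against 12 counts, ratio 231, 130 to 451) and IFIT1 (4.37 ± 1.16). CCL5 (chromosome 17, 35871491 to 35880793) rose by 6.59 ± 1.61. The integrated stress response had 12 rises and 3 falls of 35 (alone 16 and 3, median 0.51, p = 0.00406, adjusted p = 0.734 with an estimated correlation), including DDIT3 (1.82 ± 0.57) and CTH (1.48 ± 0.29), with VLDLR down (−1.96 ± 0.27). Of 15 AP-1 subunits 5 rose (alone 7, camera adjusted p = 0.0654), such as FOSB (4.53 ± 0.89), FOS (3.37 ± 0.78) and ATF3 (2.35 ± 0.64). Tubulins rose in 3 of 15 (alone 3, median 0.35, p = 0.027, adjusted p = 0.689 with an estimated correlation), TUBA4A by 2.03 ± 0.63. Mitosis genes rose in 3 of 40 (alone 0, median 0.24, p = 0.0227, adjusted p = 0.876 with an estimated correlation). Of 31 p53 targets 9 rose and 3 fell (alone 9 and 3, median −0.06, mean 0.05, camera adjusted p = 0.443), TIGAR (−1.27 ± 0.28) and ZMAT3 (−1.05 ± 0.24) among the falls. Epithelial markers rose in 7 of 9 (alone 8, median 5.28, p = 4.36e-10, adjusted p = 0.184 with an estimated correlation), among them KRT8 (1.55 ± 0.21), CLDN4 (5.28 ± 0.72, 24 against 7 counts, ratio 27.2, 11.4 to 74.7) and the cadherin CDH1 (5.30 ± 0.90, 21 against 7, 23.8, 9.74 to 66.2). A375 transcripts stood in the M14 MBZ libraries at 2.06 to 6.07% of their A375 level, against 0.277 to 0.465% in the M14 DMSO libraries, and CDH1 lay at 0.179 CPM in A375 DMSO.

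The muscle protein gene TTN (6.67 ± 1.69) and the crystallin CRYBA1 (4.44 ± 1.44) completed the largest rises. TTN stood at 23.8 ± 36.5 CPM after MBZ, an SD above its mean. MATN2 (−2.52 ± 0.52), OLFML2A (−2.31 ± 0.30), ADCY1 (−2.15 ± 0.24) and KREMEN1 (−2.09 ± 0.28) completed the largest falls. FOSL1 (0.94 ± 0.32) and CXCL8 (1.30 ± 0.42) rose. MDM2 (−0.33), CCNB1 (0.45), MKI67 (−0.38), TUBB (0.40), TUBA1B (0.28), DUSP6 (−0.16) and HMGCS1 (0.75) did not pass (adjusted p 0.095 to 0.622). In total 1225 genes rose and 1932 fell. DESeq2 called 1965 and 1754, and with thinned counts 841 rose and 937 fell, with a median shift of 0.16. Leaving out 1 of 6 libraries ended the call of CRYBA1 in all 6 cases, those of DDIT3 and CXCL8 in 5, of IFIT1, FOSL1, ATF3 and TUBA4A in 4, of CCL5 and TTN in 3, and of OASL in 1, that without M14 MBZ replicate 2. CXCL8 also missed the threshold without the library labelled M14 QNC replicate 1 (adjusted p = 0.0506).

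**Figure D4:**
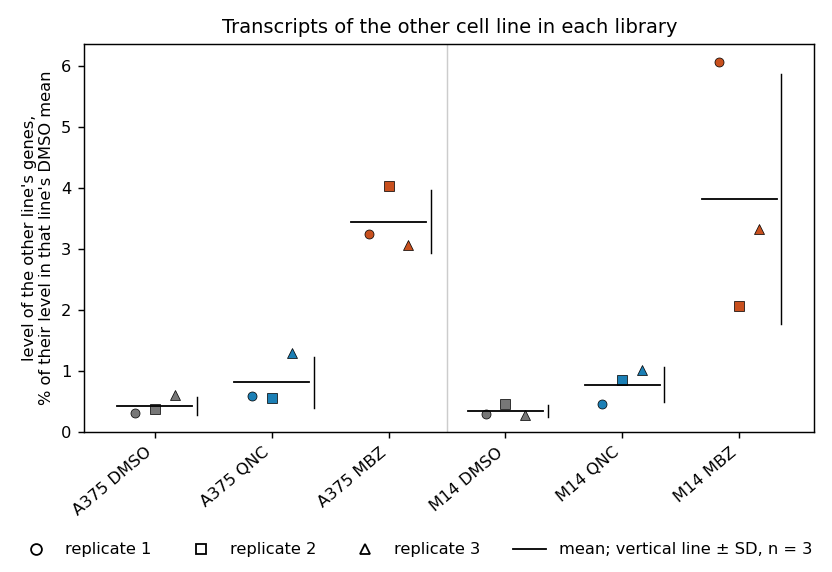
Median level of the other line's genes in each library, as percent of their level in that line's DMSO libraries. Genes are those at least 100 times higher in the other line and at least 20 CPM there.

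MBZ against QNC in A375: how do the compounds compare at the same dose and time? Mitosis genes were higher after MBZ, all 40 tested (alone 40, median 2.06, camera adjusted p = 1.48e-60, adjusted p = 0.12 with an estimated correlation), for example MKI67 (2.71 ± 0.21) and KIF20A (2.66 ± 0.21). Also higher were 17 of 42 DNA replication genes (alone 17, 1 lower, median 0.62, p = 0.000623, adjusted p = 0.825 with an estimated correlation). So were 14 of 23 histone genes (alone 15, median 1.47, p = 5.03e-06, adjusted p = 0.662 with an estimated correlation). Of 31 p53 targets 13 were lower (alone 14, 1 higher, median −0.47, p = 0.000366, adjusted p = 0.353 with an estimated correlation), among them PHLDA3 (−1.53 ± 0.25), TIGAR (−1.50 ± 0.23) and RRM2B (−1.45 ± 0.18). TUBB (1.33 ± 0.23) and TUBA1B (1.41 ± 0.32) were higher, with 4 of 15 tubulins higher and 1 lower (alone 4 and 1, camera adjusted p = 0.376). Heat shock genes were higher after MBZ in 11 of 21 and lower in 1 (alone 11 and 2, median 0.52, p = 0.00134, adjusted p = 0.542 with an estimated correlation). ER chaperones were higher in 9 of 24 and lower in 1 (alone 12 and 1, median 0.53, p = 0.00846, adjusted p = 0.645 with an estimated correlation).

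Ribosomal proteins were higher after MBZ than after QNC in A375 in 44 of 68 (alone 53, median 0.54, p = 2.36e-10, adjusted p = 0.663 with an estimated correlation). The mitochondrial genome was higher in 10 of 13 (alone 10, median 1.68, p = 0.00018, adjusted p = 0.645 with an estimated correlation). The matrix protein CCN1 (chromosome 1, 85580761 to 85583962) differed by 4.27 ± 0.89, MIR222HG by 3.99 ± 0.42, FOS by 3.83 ± 0.81, and the U1 copies RNVU1-28 and RNU1-28P by 4.02 ± 0.65 and 3.48 ± 0.68. The zinc finger genes ZNF28 (−2.52 ± 0.22) and ZNF629 (−2.37 ± 0.27), SHISA2 (−2.19 ± 0.23), NAT8L (−2.15 ± 0.31) and INTS5 (−2.12 ± 0.25) were lower. In all 2409 genes were higher and 2198 lower (2248 and 3701 without the filter, median shift −0.24).

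In M14, ER chaperones were lower after MBZ than after QNC in 11 of 24 (alone 13, median −0.53, camera adjusted p = 2.01e-06, adjusted p = 0.347 with an estimated correlation), such as SEL1L (−1.68 ± 0.16), DNAJC3 (−1.40 ± 0.21) and MANF (−1.32 ± 0.25). Heat shock genes were higher in 13 of 21 and lower in 1 (alone 14 and 1, median 0.98, p = 8.49e-09, adjusted p = 0.184 with an estimated correlation), with DNAJB1, an HSP70 partner, at 3.44 ± 0.67. Ribosomal proteins were higher in 59 of 68 (alone 65, median 0.70, p = 9.51e-29, adjusted p = 0.473 with an estimated correlation). Mitochondrial genome genes were higher in 7 of 13 (alone 12, median 1.60, p = 9.85e-09, adjusted p = 0.473 with an estimated correlation). Oxidative phosphorylation genes were higher in 9 of 47 (alone 9, median 0.40, p = 2.64e-06, adjusted p = 0.777 with an estimated correlation). Mitosis genes were higher in 7 of 40 (alone 13, median 0.53, p = 2.59e-06, adjusted p = 0.7 with an estimated correlation). Glycolysis and hypoxia genes were lower in 11 of 32 with 1 higher (alone 13 and 2, median −0.54, p = 0.00563, adjusted p = 0.473 with an estimated correlation). Epithelial markers were higher in 4 of 9 (alone 5, median 2.15, p = 4.12e-05, adjusted p = 0.473 with an estimated correlation). The receptor kinase AXL (2.70 ± 0.64) and TXNIP, a thioredoxin inhibitor (2.24 ± 0.35), stood next to MT-CO3 (2.13 ± 0.28) and MT-CO1 (2.11 ± 0.37) among the higher. Among the lower were EN2 (−2.40 ± 0.27), RASSF2 (−2.31 ± 0.39), HS6ST1 (−2.12 ± 0.31), APOLD1 (−2.09 ± 0.32) and SEMA6B (−2.07 ± 0.38). In total 1089 genes were higher and 1823 lower, against 1676 and 1770 with DESeq2.

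Did the lines respond differently? For QNC the difference M14 minus A375 passed for 208 genes higher and 51 lower, led by mitosis genes, 35 of 40 higher (alone 39, median 1.68, camera adjusted p = 2.52e-73, adjusted p = 0.118 with an estimated correlation), such as UBE2C (2.76 ± 0.32) and PLK1 (2.37 ± 0.28). CEBPD, a stress-induced transcription factor (chromosome 8, 47736909 to 47739086), differed by 3.06 ± 0.54 and ACAD10 (chromosome 12, 111686056 to 111757107) by −1.55 ± 0.26. Without the library labelled M14 QNC replicate 1 the numbers were 845 and 857, and 21 of 33 melanocyte lineage genes passed as lower in the M14 response (alone 26, median −1.38, p = 9.36e-24, adjusted p = 0.00876 with an estimated correlation). For MBZ 389 genes passed as higher and 559 as lower. Glycolysis and hypoxia genes were lower in 10 of 32 and higher in 1 (alone 15 and 1, median −0.67, p = 2.26e-07, adjusted p = 0.12 with an estimated correlation), including PDK1 (−1.99 ± 0.29) and ADM (−2.55 ± 0.42). Melanocyte lineage genes were lower in 11 of 33 (alone 19, median −1.40, p = 4.52e-13, adjusted p = 0.473 with an estimated correlation), and in 4 with the other line's share subtracted. That subtraction removed more than the estimated share.

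Called genes were compared between comparisons. For MBZ, 441 genes rose in both lines (153 by the product of the 2 numbers over genes tested) and 759 fell in both (238), while 70 went opposite ways (392), with r = 0.28 across genes, which are not independent replicates. For QNC the 7 genes called in M14 are too few to show sharing (0 shared, 0.0582 by the product), and without the library labelled M14 QNC replicate 1 the shared numbers were 14 higher (13.3) and 22 lower (28.5), with 55 opposite (39.3). Within A375, 29 genes rose (16.3) and 49 fell (39.8) after both compounds, and 26 went opposite ways (56.4). Within M14, 3 rose (0.544) and 0 fell. Comparisons within a line use the same 3 DMSO libraries, which by itself correlates the changes. The covariance across genes was 0.123 in A375, against 0.0791 for simulated unchanged groups that share simulated DMSO libraries, and 0.333 in M14, against 0.0756. The simulated values are means over drawn controls, not the value for the 3 real DMSO libraries. The correlation was 0.187 in A375, below the 0.378 of the simulated groups, and 0.443 in M14, above their 0.270. With 3 controls no independent groups of 2 could be formed, so part of the shared changes may come from the shared controls.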

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

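In the tests below, the exchange of labels and the fixed number of foreign reads were chosen only after the result was seen. All values in the next 2 paragraphs were flagged because the response of M14 minus that of A375 to the same compound passed the test of the difference itself. They are log2 values ± SE, 3 libraries per group.

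For QNC 259 genes passed. Lists whose median difference was higher in M14 were mitosis (1.68), DNA replication (0.40), tubulins (0.66), integrated stress response (0.44), ER chaperones (0.72), NF-kB and cytokines (0.78), interferon response (0.93), MAPK output (0.47), AP-1 subunits (1.40), dedifferentiated melanoma (0.42), YAP and SRF targets (0.21) and histone genes (1.37). Lower were lysosome (−0.52), V-ATPase (−0.24), melanocyte lineage (−0.75) and oxidative phosphorylation (−0.59). None of these 16 lists passed with an estimated correlation (adjusted p 0.118 to 0.807). Cell division genes that fell in A375 and did not pass in M14 were UBE2C (2.76 ± 0.32), NEK2 (2.47 ± 0.30), PLK1 (2.37 ± 0.28) and KIF20A (2.09 ± 0.27), and the histone genes H1-5 (2.34 ± 0.38) and H2AX (2.11 ± 0.45) differed too. Further genes were RGPD5 (3.61 ± 0.74), the spliceosomal RNU4-2 (3.07 ± 0.70), CEBPD (3.06 ± 0.54), SCARNA10 (2.86 ± 0.49), the histone gene H3C8 (2.78 ± 0.65), XBP1 (1.40 ± 0.35) and HSP90B1 (1.07 ± 0.26). The difference was below 0 for LINC01443 (−2.74 ± 0.71) and OCA2 (−2.36 ± 0.55), mostly from A375, where they stood near the floor at 24 and 22 counts after QNC against 5 and 7 in DMSO. It was also below 0 for FXYD3 (−1.73 ± 0.41), MIR3681HG (−1.71 ± 0.36), ACAD10 (−1.55 ± 0.26) and the lysosomal glucosidase GAA (−1.49 ± 0.33). Leaving out 1 of 12 libraries ended the calls of RNU4-2, H3C8 and FXYD3 in 11 cases, OCA2 in 10, LINC01443, H2AX, HSP90B1 and XBP1 in 9, RGPD5 in 8, GAA in 6 and MIR3681HG in 3. Of 100 splits of the libraries within the lines, out of 200 possible, 1, the real one, gave as many genes. The highest other gave 234. That other split exchanges all 3 M14 libraries between QNC and DMSO and leaves A375 as it is, so it keeps the A375 response. Further splits that keep the A375 groups whole gave 76 to 186 genes, and splits that mix them gave at most 4. The count thus mostly follows the A375 response and does not decide whether the difference between the lines arose by chance.

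For MBZ 948 genes passed. Higher in M14 by list median were tubulins (0.30), heat shock (0.55), AP-1 subunits (0.86) and epithelial markers (3.61), and lower were lysosome (−0.59), ER chaperones (−0.53), melanocyte lineage (−1.40) and glycolysis and hypoxia (−0.67). Adjusted p was 0.12 to 0.807 with an estimated correlation. The genes were SNPH (7.25 ± 0.94, on 11 against 2 counts in M14), the desmosome protein DSP (5.65 ± 0.78), AFAP1L2 (5.37 ± 0.88), GALNT5 (5.18 ± 0.63), CDCP1 (4.82 ± 0.77), CLDN4 (5.72 ± 0.87), TUBD1 (1.99 ± 0.47) and the chaperone partner BAG3 (1.496 ± 0.42). In M14 MBZ SNPH stood at 1.81 CPM, DSP at 6.65, AFAP1L2 at 1.70, GALNT5 at 4.69 and CDCP1 at 10.2. SNPH lay at 34.6 CPM in A375 DMSO, and A375 transcripts stood in these libraries at 2.06 to 6.07% of their A375 level. The rise of SNPH in M14 thus cannot be told apart from RNA or reads of the other line. The difference was below 0 for LY75 (−6.45 ± 1.18), MLANA (−5.39 ± 1.06), GPR143 (−5.14 ± 0.87), KCNH1 (−4.65 ± 0.90), LINC01443 (−4.42 ± 0.83), OCA2 (−4.08 ± 0.57), PMEL (−3.25 ± 0.50), ADM (−2.55 ± 0.42), PDK1 (−1.99 ± 0.29), SEL1L (−1.49 ± 0.21), PSAP (−1.44 ± 0.32) and P4HA1 (−1.19 ± 0.25). In A375 some of these stood near the floor, LY75 at 62 counts after MBZ against 8 in DMSO, GPR143 at 59 against 12, OCA2 at 19 against 7 and LINC01443 at 12 against 5. Leaving out 1 of 12 libraries ended the call of BAG3 in 9 cases and that of TUBD1 in 1. With the other line's share subtracted LY75, GPR143, KCNH1, LINC01443, PMEL and OCA2 changed sign. That subtraction removed more than the estimated share, so these signs cannot be read as changes. Of 100 splits, out of 200 possible, 5 gave as many genes, the real one included, and the highest other gave 1550, so chance is not excluded by this count. All 4 others exchange 2 of 3 libraries in 1 line and none in the other, which adds up what the lines share and points to a structure of the samples.

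With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each of 7 comparisons 1 split, the real one, gave the number called. Real value and highest other were 454 and 0 for QNC in A375, 3906 and 1 for MBZ in A375, 7 and 0 for QNC in M14, 3157 and 0 for MBZ in M14, 4607 and 0 for MBZ against QNC in A375, 2912 and 123 for the same in M14, and 7662 and 0 for the DMSO groups.

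The first pattern weighed is that the library labelled M14 QNC replicate 1 lies near the M14 DMSO libraries. Depth is argued against: with all libraries thinned to 1 total its correlation was 0.975 with DMSO and 0.951 with the other QNC libraries, a margin of 0.0249. Exchange with an M14 DMSO library needs a partner out of place, and each DMSO library correlated more with DMSO than with QNC replicates 2 and 3, by at least 0.0225. A DMSO library under a QNC label, or a culture that did not respond, may account for it: the share of the other libraries' response in it was 0.105, above the highest left-out DMSO library (0.0445). The 95% interval of its share, 0.0867 to 0.124, comes from resampling the 2127 genes and does not measure the spread between libraries. These genes were called against the same DMSO libraries, which can pull the DMSO shares towards 0. Replicate 1 took no part in that choice, so its share and theirs are not a like comparison. Genes called over all 18 libraries go against a DMSO library, SNORD3A at 1957 CPM in it (at most 693 in DMSO), RPPH1 at 9391 (5683), SCARNA10 at 99.0 (36.4) and SLC7A11 at 62.0 (44.8), but they were called with this library in the treated group and do not decide. Of the 14 genes fixed in advance, CDKN1A, MDM2, MKI67, TUBB, TUBA1B, PMEL, DUSP6, DDIT3, CXCL8 and HMOX1 lay beyond all DMSO libraries. Each lay on the side of the mean of the other QNC libraries. Examples were CXCL8 (67.4, at most 38.9 in DMSO), DUSP6 (112, 97.2), TUBB (606, at least 783) and MKI67 (135, 161). Some margins were small, as for CDKN1A (9.25, at most 9.02) and DDIT3 (71.3, 70.3). CCNB1, MITF, FOSL1 and HMGCS1 lay within the DMSO range, and none of the 14 beyond it on the other side. Genes called without this library went both ways. DCT (1942, at most 1933) and S100B (106, 102) lay beyond DMSO on the other side, and CTSA (83.2, at least 95.2) towards QNC. The 14 genes thus leaned towards QNC, but this rests on 1 library. A DMSO library, a culture that did not respond and, untested, a weaker or later response cannot be told apart here.

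The second pattern is the rise of the other line's genes in the MBZ libraries, above all DMSO libraries for all 21 M14 genes in A375 and 46 of 64 A375 genes in M14. These genes were picked as scarce in the same DMSO libraries, which can favour values above them. After QNC 3 of 21 in A375 and 15 of 64 in M14 lay above all DMSO libraries, and 0 below. A rise of all scarce transcripts in proportion to their level was not tested, since rises in CPM were compared and genes near 0 add little. A rise of all by a like number of CPM is argued against: over all protein-coding genes in the file, those scarce in both lines rose by 5.75% of the rise of the other line's genes in A375 and by 5.42% in M14. The same test on filtered genes (68.1% and 38.4%) and the correlation on them (Spearman −0.274 and −0.0530) are void, and the bound set for them was wrong, since all 399 tested genes scarce in both lines passed the filter only through treated libraries. RNA or reads of the other line stay open and cannot be told apart from a change in the cells (Spearman over all genes 0.231 in A375 and 0.157 in M14, where every abundant gene would have to follow, and genes scarce in A375 such as CDH1 rose in M14 too). A fixed number of foreign reads per library, which could matter more in shallow libraries, stays open in M14 (0.650-fold). In A375 counts on these genes grew 1.80-fold, from 167 to 227 per library in DMSO to 311 to 370 after MBZ. The A375 QNC libraries ranged from 137 to 512, so this argues against it only weakly there.

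The third pattern is the rise of ribosomal protein genes and the mitochondrial genome after MBZ. For non-coding RNA taking counts, medians with protein-coding genes only were 0.566 and 2.00 in A375 and 0.680 and 2.03 in M14. That fit moved all log2 fold changes nearly alike (median shift 0.074 and 0.115, r = 0.99998 and 0.99995 with the main fit). So the rise does not come from how non-coding counts enter the scaling, and the test shows no more than that. In thinned libraries medians were 0.573 and 1.91 in A375 and 0.735 and 2.04 in M14. Thinning keeps each gene's expected share of counts, so these medians hardly could have changed and depth stays open. Length and expression level, by the excess over 10000 matched random lists, are argued against for the mitochondrial genome (1.52 in A375, 1.62 in M14) and for ribosomal proteins in M14 (0.536), while in A375 the ribosomal median (0.494) lies above the central 95% of the matched lists (0.0347 to 0.302) but its excess of 0.2996 just misses the bound of 0.3 set beforehand, so they stay open there. For the mitochondrial genome the match was loose, with a median distance of 0.793 log2 in expression and 0.485 log2 in length. The random lists also do not carry the correlation between its genes. A response of the cells to MBZ stays open as a hypothesis, found and tested on the same data, beside RNA quality, which was not measured.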

How the results depend on the processing

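Chosen after seeing the data were the fits on 17 libraries, on thinned counts, on protein-coding genes only and on counts with the other line's share subtracted. Directions of named genes mostly held: no value past the threshold changed sign with DESeq2, RLE factors, limma voom, no filter, the replicate block, only the libraries compared, or any library left out, while some values near 0 that had not passed did, such as DDIT3 and HMGCS1 for QNC in A375 and CCNB1 and TUBB for MBZ in A375. Of 409 named values 373 kept their side of the threshold with DESeq2 (35 gained it, 1 lost it), 391 with limma voom (18 lost), 363 without a filter (31 gained, 15 lost), 384 with the replicate block (25 lost) and 341 without the library labelled M14 QNC replicate 1 (64 gained, 4 lost). Leaving out each library in turn kept 2421 of 2754 values, with 272 lost and 61 gained. In simulated counts 52 of 100 genes changed 2-fold were recovered for QNC in A375 and 55 for MBZ in M14, so changes of that size can be missed, and depth alone was not varied there. Where no cause is given below, the cause was not tested.

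Signs turned with the other line's share subtracted: PMEL −3.85, OCA2 −3.59 and GPR143 −4.54 for MBZ in A375, and LY75 2.52, GPR143 3.68, KCNH1 2.64, LINC01443 1.71, PMEL 2.29 and OCA2 2.92 for the difference between lines after MBZ. The subtraction by construction lowers genes that the other line holds at a high level. It also removed more than the estimated share from the MBZ libraries, so these turned signs cannot be read as changes. With thinned counts the difference between lines after QNC turned for LINC01443 (1.38 with 18 libraries, 0.96 with 17) and OCA2 (2.00 and 1.74), and the cause was not tested.

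Counts that moved by over 1.5 times follow as higher and lower genes. With DESeq2: QNC in A375 359 and 487, QNC in M14 267 and 95, MBZ in M14 1965 higher, MBZ against QNC in M14 1676 higher, difference between lines 499 and 222 for QNC and 820 higher for MBZ. Without the filter: QNC in A375 206 and 486, QNC in M14 310 and 269, MBZ in A375 3653 lower, MBZ against QNC in A375 3701 lower, difference between lines 456 and 201 for QNC and 649 higher for MBZ. With limma voom: QNC in A375 240 higher, difference for QNC 117 lower. With only the libraries of the line or groups compared: QNC in M14 20 higher, difference for QNC 384 and 82. With the replicate block: QNC in A375 64 higher, difference for QNC 23 lower, difference for MBZ 237 and 367. With protein-coding genes only: QNC in M14 0 higher (edgeR). With the share subtracted: difference for QNC 20 lower, for MBZ 253 higher.

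Without the library labelled M14 QNC replicate 1: QNC in A375 225 higher, QNC in M14 954 and 1191, difference for QNC 845 and 857, difference for MBZ 886 lower. Thinned counts, with fewer reads by construction, gave for 18 and then 17 libraries: QNC in A375 37 and 171, then 64 and 192; MBZ in A375 856 and 663, then 999 and 761; QNC in M14 8 and 2, then 407 and 433; MBZ in M14 937 lower, then 1068. MBZ against QNC gave 1183 and 839, then 1308 and 941 in A375, and 979 lower, then 985 in M14. The difference for QNC gave 104 and 12, then 433 and 271, that for MBZ 121 and 170, then 152 and 246, and the DMSO groups 2210 and 2484, then 2349 and 2625.

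Leaving out each library in turn gave these ranges, higher and lower: QNC in A375 26 to 257 and 151 to 350, QNC in M14 2 to 954 and 0 to 1191 (edgeR), MBZ in M14 791 to 1272 higher, MBZ against QNC in M14 650 to 1111 higher, difference for QNC 92 to 845 and 8 to 857, difference for MBZ 224 to 588 and 310 to 785. The highest values of QNC in M14 and of the difference for QNC come from leaving out the library labelled M14 QNC replicate 1.

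Shared genes, higher and lower: QNC in both lines 3 and 2 with DESeq2, 14 and 22 with 17 libraries. MBZ in both lines gave 728 higher with DESeq2, and 268 and 145 at 2-fold or more. Both compounds in A375 gave 83 and 84 with DESeq2, 57 higher with 17 libraries, and 11 and 20 at 2-fold or more. Both compounds in M14 gave 128 and 37 with DESeq2, and 331 and 541 with 17 libraries. Of the 95 list tests past the threshold 1 passed with an estimated correlation, mitosis after QNC in A375.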

Other observations

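All tests of lists here were fixed before the data were examined. Some gene groups moved in ways not described above. Autophagy genes were lower after MBZ than after QNC in A375, 8 of 34 with 1 higher (alone 8 and 1, median −0.30, camera adjusted p = 0.023, adjusted p = 0.202 with an estimated correlation), among them NBR1, a cargo receptor (−0.90), and WIPI2, of autophagosome formation (−0.83). Matrix genes differed between MBZ and QNC in M14, 9 of 30 higher and 5 lower (alone 9 and 6, median 0.71, adjusted p = 0.0223, adjusted p = 0.56 with an estimated correlation). In M14 after MBZ 2 of 23 histone genes rose (alone 2, median 0.49, adjusted p = 0.0117, adjusted p = 0.841 with an estimated correlation).

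In M14 after MBZ 3 genes, picked from their lists after their values were seen, rose: EREG, an EGF receptor ligand (5.95 ± 0.87), AREG (5.61 ± 0.98, 25 against 7 counts, ratio 28.3, 11.9 to 77.6), and EGFR (5.15 ± 0.67, 35 against 12, 23.1, 11.7 to 48.9). Of the 29 MAPK output genes, among them EREG and AREG, 4 rose and 5 fell (alone 5 and 6, median −0.04, mean 0.61, test higher, camera adjusted p = 0.605). In DMSO, M14 held more of 19 of 39 lysosome genes and less of 5 (alone 20 and 5, median 0.67, adjusted p = 0.0231, adjusted p = 0.841 with an estimated correlation), with the protease CTSD at 3.85 and CTSK at −5.07. M14 also held more of 9 of 18 V-ATPase genes (alone 9, median 0.50, adjusted p = 0.0299, adjusted p = 0.757 with an estimated correlation) and of 39 of 68 ribosomal proteins with 1 lower (alone 40 and 1, median 0.53, adjusted p = 0.000592, adjusted p = 0.841 with an estimated correlation).

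Other line's genes stood at 0.592, 0.560 and 1.30% of their level in the A375 QNC libraries and at 0.452, 0.857 and 1.01% in the M14 QNC libraries. The 3 non-coding genes with an identical value took 14.5 ± 5.73% of counts in M14 MBZ and 3.46 to 5.15% in the other groups. Signal recognition particle, 7SK, RNase P and RNase MRP RNA together took 9.68, 11.7 and 14.8% of counts in A375 (DMSO, QNC, MBZ) and 7.21, 16.6 and 10.4% in M14. These RNAs lack long poly(A) tails, and the kit named in the protocol primes on such tails.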
